A study of Sus scrofa with 18 samples.

How the data were processed

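Intestinal tissue of female mixed-breed pigs was profiled with droplet single-cell RNA sequencing (10x Chromium) and with spatial transcriptomics on Visium slides, on which tissue sections lie over spots that each capture RNA from a small area. The labels give an age of 8 weeks and the design text 7.5 weeks. The distal ileum, which carries a continuous Peyer's patch, was compared with jejunum taken at a discrete Peyer's patch. Each assay held 3 ileum and 3 jejunum samples, numbered 2, 3 and 4 in the labels. Each single-cell library was registered as 2 samples, its 2 sequencing runs. Their counts stand in 1 matrix, so a library was 1 replicate. The labels do not say that a number marks 1 animal. P-values measure the spread between these samples.

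Per the labels' protocols, tissue for single cells was stripped of its muscularis, digested and enriched for lymphocytes on a density gradient, so shares of cells describe that fraction and not the tissue. Tissue for the sections was embedded and frozen. The deposited matrices hold UMI counts per gene and barcode with no normalization. The submitters' processing notes name Cell Ranger 6.1.2 and Space Ranger 1.3.0, with the file headers giving matrix format 2. The genome build is not given in the sources used here, so no coordinates are given. The matrices list 25880 features. Of these, 18247 carried a symbol in the files and 119 more were named from a reference table of pig genes, in which 13945 of the IDs were found. The other 7514 keep their IDs.

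All single-cell barcodes were deposited, empty ones included. Barcodes with at least 1000 UMIs, 500 genes and at most 12.5% mitochondrial UMIs were kept. The mitochondrial limit removed 4.30% to 6.99% of barcodes in the ileum libraries and 11.1% to 12.7% in the jejunum libraries. Doublets were scored with the Scrublet method in scanpy 1.11.5. Those called made up 2.00% to 3.55% of barcodes and were removed. The thresholds marked only 27.2% to 34.7% of simulated doublets, so doublets may remain among the cells kept. In ileum 2 the automatic threshold marked 0.0615% of barcodes and was replaced by the middle threshold of the other libraries, which marked 2.77%. This left 43910 cells, 6357 to 8289 per library, with a median of 4327 to 5915 UMIs per cell. Total UMIs per library ran from 65226864 to 78823412.

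The section files give the number of spots over tissue and their positions, but the positions carry no barcodes. The spots over tissue were therefore taken as that many barcodes with the highest UMI totals in each section. This gave 10021 spots, 1174 to 2234 per section, with a median of 15036.5 to 23189.5 UMIs. Total UMIs per section ran from 37784871 to 51854325. The file of ileum section 2 carries a capture-area letter in its name that differs from its label, and its sample was taken from the deposition record. All ileum sections lay on 1 slide and all jejunum sections on another, so slide and tissue cannot be told apart in the spatial data.

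Cells were clustered with the Leiden method (leidenalg 0.10.2) on 2000 variable genes, 30 principal components and 20 neighbours at resolution 1.0. The 36 clusters were named from marker lists fixed before the data were examined. A name needed at least 3 raised markers, and 1 cluster stayed unnamed. Spots were clustered at resolution 0.6, and regions were named by number and leading genes. Because most regions held spots of few sections, spots were also clustered after centring and scaling each gene within its section, at resolution 0.3. This was chosen after seeing the data, and these regions differ from the main ones in resolution too. A class or region was tested only with at least 20 cells or spots in each of the 6 samples.

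Counts were summed per library or section and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Positive log2 fold changes are higher in ileum, and the error given beside them is a standard error. CPM values are given as mean ± SD with n = 3 per tissue. The difference between the changes of B-like and T/ILC-like cells was tested as an interaction, with the library as a block. The 27 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Shares were compared with 2-sided exact permutation tests, for which 3 against 3 samples cannot go below p = 0.1. Genes were named from the top of each part of a rule fixed before the data were examined, and not all that it gives are named. It takes the 10 largest changes per direction among called genes with a mean of at least 10 CPM and no overlap between tissues, then the members with the smallest p of each list, 4 for a called list and 2 for another. Immunoglobulin and T cell receptor segments are left out of the first part, and 1 gene near the top of a part is not reported here.

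The replicate numbers were checked for pairing by correlating the deviations of equally numbered ileum and jejunum libraries from their tissue means. For all cells the correlations were 0.48, 0.42 and 0.64, and each library correlated best with its own number. Every tested cell class, section region 3 and section-centred region 10 also passed the bound of 0.1. The pairing is thus inferred from the data and not from the labels. Counts with the replicate number as a block are given beside results that they move. No pair of samples of 1 group agreed within counting noise (chi-square of 34.4 to 234 per degree of freedom), so none was merged. This does not show what lies behind the spread between them.

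The alternatives were another scaling, DESeq2 1.42.0, no filter on low counts, each sample left out, the replicate block, stricter and looser cell filters, doublets kept, subtraction of free RNA measured in barcodes under 100 UMIs, other clustering resolutions, and spots with at least 1000 UMIs. The share of free RNA subtracted was the CPM of epithelial markers in lymphocytes over that in those barcodes, 1.28% to 2.31% per library. Some alternatives were added after seeing the data. These are single clusters of a class, subtraction of a T/ILC-like profile from B-like sums, and list tests on corrected sums. Tests on simulated counts recovered 41.8% of genes changed by a fold of 2 in all cells, 71.6% in B-like cells, 46.3% in antibody-secreting-like cells and 7.46% in whole sections. With a fold of 4 they recovered 80.3%, 87.9%, 93.9% and 69.7%. False calls made up 9.90% of the calls for all cells, and 4.51% (T/ILC-like cells) to 15.0% (region 3) over the tests simulated. With DESeq2 they made up 25.3% for all cells, 21.2% for B-like cells and 23.5% for whole sections.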

Results

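Ileum and jejunum containing Peyer's patches, the lymphoid follicles of the gut wall, were compared in young pigs by 2 assays. Single-cell sequencing gave 43910 cells from 3 ileum and 3 jejunum libraries after enrichment for lymphocytes. Spatial transcriptomics gave 10021 spots over tissue from 3 ileum and 3 jejunum sections. Total UMIs ranged from 65226864 to 78823412 per library and from 37784871 to 51854325 per section.

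The first comparison asked which cell classes made up the lymphocyte-enriched fraction of each tissue. B-like cells were the most frequent class and made up 74.9% ± 2.99 of ileum cells against 52.2% ± 5.02 of jejunum cells (SD, n = 3 libraries each). T/ILC-like cells, which carry T cell and innate lymphoid markers, made up 16.4% ± 3.14 in ileum and 32.9% ± 3.52 in jejunum. Myeloid-like cells were at 1.79% ± 0.889 against 4.34% ± 2.28, and epithelial-like cells at 0.627% ± 0.206 against 1.66% ± 0.413. The ranges of the tissues did not overlap for these classes, nor for mast-like and endothelial-like cells. Each of these 6 differences had p = 0.1 in the exact permutation test, the smallest it can give, and 0.15 after adjustment. The share of antibody-secreting-like cells, 3.51% ± 0.784 in ileum and 3.79% ± 0.230 in jejunum, differed by less than the spread between libraries (exact permutation p = 0.6). Jejunum library 4 held 138 of the 196 mast-like cells, and without it the mast-like difference went from -0.617 to -0.146 percentage points. The myeloid-like difference went from -2.56 to -1.25 percentage points, and the endothelial-like one from -0.382 to -0.239. The limit on mitochondrial UMIs removed 4.30% to 6.99% of barcodes in ileum libraries and 11.1% to 12.7% in jejunum libraries. Cluster 14, led by HBB and left without a name, held 2.22% of ileum and 2.76% of jejunum cells.

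**Figure D1:**
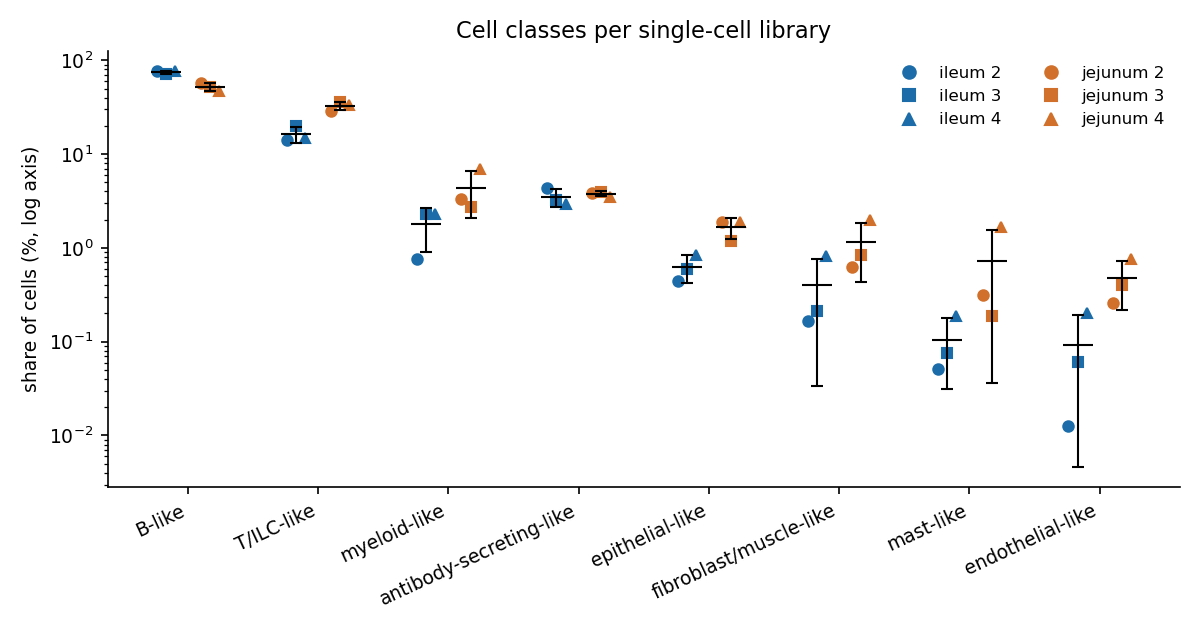
Share of cells (%, log axis) in each named class for the 3 ileum and 3 jejunum single-cell libraries; points are libraries, horizontal marks the mean and bars 1 SD, shortened where they would reach 0. B-like shares lay between 71.5% and 77.1% in ileum and between 47.6% and 57.5% in jejunum.

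Across all cells, the gene lists of B cells, germinal centres and the cell cycle were higher in ileum, and those of T cells, absorptive and goblet cells, fibroblasts and endothelium were higher in jejunum, by camera at the preset correlation. With an estimated correlation no list passed (lowest adjusted p = 0.309). Few members were called in some of them, 1 of 23 for absorption, 2 of 9 for goblet cells and 1 of 14 for fibroblasts. The largest changes toward ileum were those of LIX1, ALOX15 and CLVS2, at 1.51, 1.51 and 1.42, among genes of the naming rule. FADS3, a fatty acid desaturase family gene, was at 244.6 ± 11.1 CPM in ileum and 98.7 ± 19.8 in jejunum (log2 fold change 1.31 ± 0.14, edgeR adjusted p = 0.010). Of the germinal centre list, ELL3 changed by 0.64 and CD38 by -1.07, and MYBL1, a transcription factor of germinal centre B cells, was at 135 ± 5.62 against 81.9 ± 7.99 CPM. JCHAIN, which joins secreted immunoglobulin into polymers, was higher in jejunum by a log2 fold change of -1.84 ± 0.18 (adjusted p = 0.0097). TNFRSF17, the BCMA receptor of plasma cells, was at 8.94 ± 1.66 CPM in ileum and 29.4 ± 2.56 in jejunum. SPINK1, a trypsin inhibitor, changed by -3.73, the chemokine genes CCL11, CCL3L1 and CCL2 by -2.15, -2.12 and -1.80, and GNB5 and RHEX by -2.00 and -1.92. The hormone genes GCG and SST were at 0.106 and 0.810 CPM in ileum and at 69.5 and 162 CPM in jejunum. In whole sections GCG changed by -0.17. CD4 was at 8.38 ± 0.351 against 21.4 ± 0.751 CPM and CD8A at 25.8 ± 2.70 against 49.1 ± 4.27 CPM.

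In that test 1741 of 13921 genes passed the threshold in edgeR, 849 higher in ileum and 892 higher in jejunum. With the replicate number as a block there were 4936, and DESeq2 called 3346. Leaving out jejunum 4 gave 224 genes, ileum 3 gave 288, jejunum 2 gave 394, ileum 2 gave 666, jejunum 3 gave 1077 and ileum 4 gave 1437. Of these calls 31.6% (without ileum 4) to 54.1% (without ileum 2) were higher in ileum, against 48.8% with all libraries. Values of the 2 tissues did not overlap for 40.6% of genes, where chance gives 10%. These sums follow the shares of the classes as well as levels within them.

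Of the 27 gene lists tested in all cells, 22 passed camera at the preset correlation and 0 with an estimated one. The lists for B cells, germinal centres and the cell cycle were higher in ileum, with medians of 0.48, 0.52 and 0.38, and the other 19 were higher in jejunum. In the cell cycle list all 27 members had positive changes, 13 of them past the threshold and 24 when adjusted over the list alone. In the T cell list 13 of 17 members were called higher in jejunum, and 16 when adjusted over the list alone. The antimicrobial list was no longer called with the replicate block (adjusted p = 0.055).

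**Figure D2:**
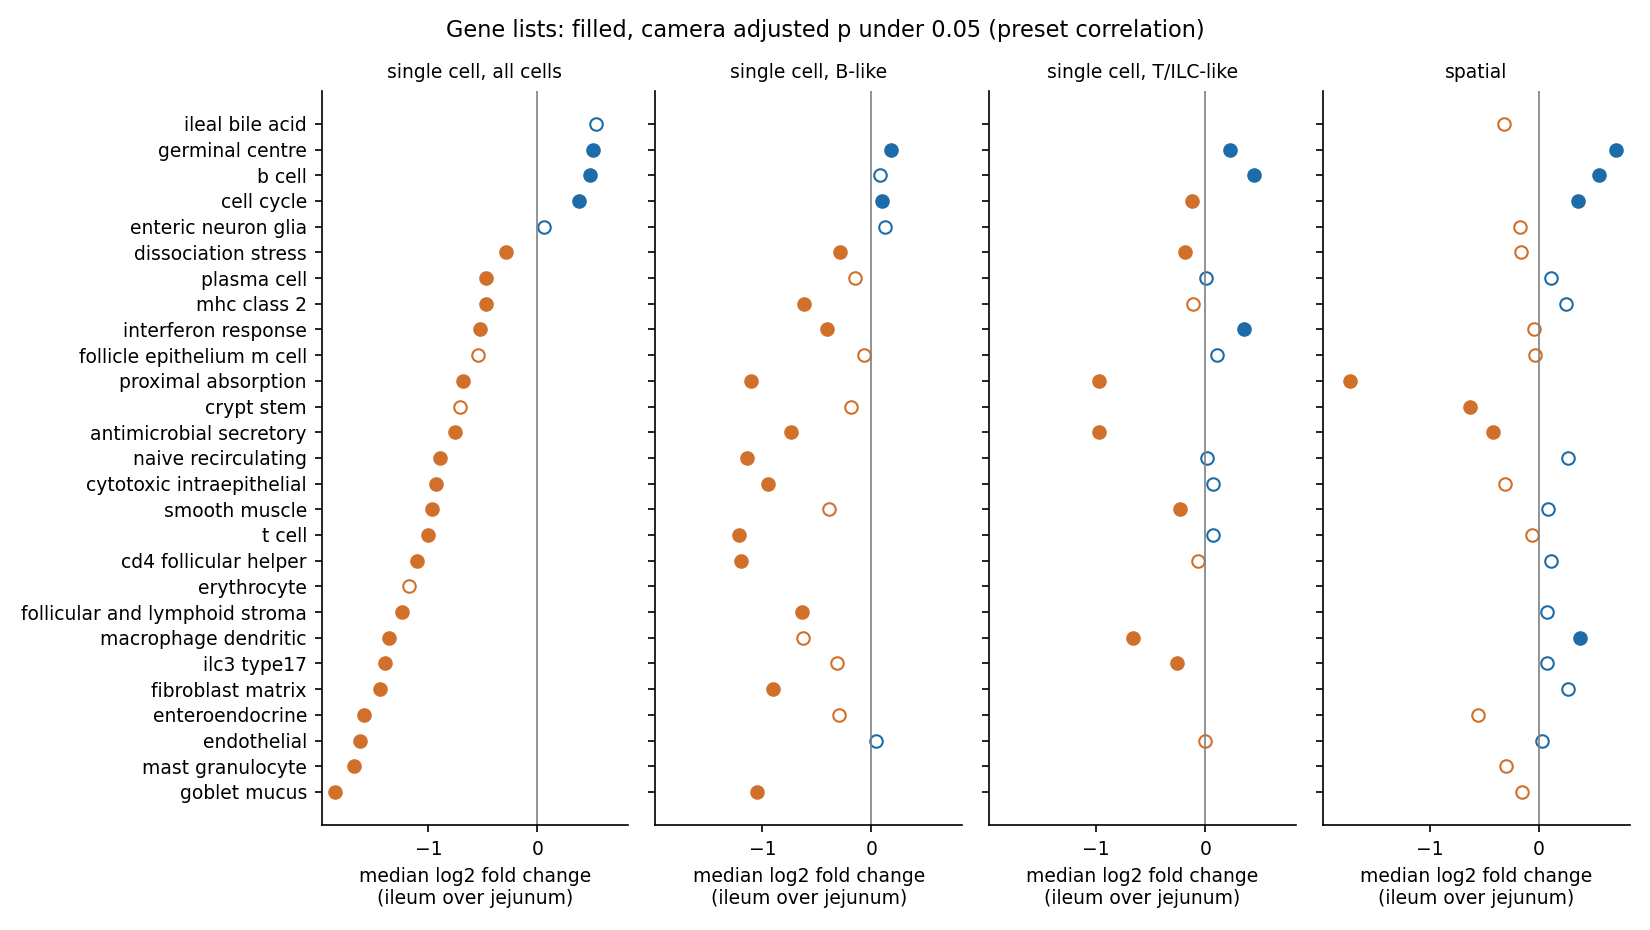
Median log2 fold change (ileum over jejunum) of each gene list in all cells, B-like cells, T/ILC-like cells and whole sections; filled points had a camera adjusted p under 0.05 at the preset correlation. The proximal absorption list lay at -1.74 in sections, and the germinal centre list at 0.70.

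Within B-like cells most of the genes called were higher in jejunum. FADS3 was at 285 ± 3.68 CPM in ileum and 150 ± 29.5 in jejunum (log2 fold change 0.92 ± 0.13, edgeR adjusted p = 0.032), and MAPK4 at 103 ± 4.94 against 62.3 ± 7.36. PMEPA1 and TYROBP changed by 0.75 and 0.73. The DNA- and RNA-binding gene YBX3 was at 17.1 ± 0.806 CPM in ileum and 60.1 ± 1.72 in jejunum (log2 fold change -1.82 ± 0.07, adjusted p = 0.00014). GNB5, PADI2, FAM129A and SCIMP changed by -2.56, -2.47, -1.96 and -1.59, and IL2RA, a chain of the interleukin receptor of activated lymphocytes, by -1.72. GNLY, a cytotoxic granule gene, changed by -1.83, and after subtraction of free RNA by -2.92 without being called (adjusted p = 0.46). CCR9, a receptor for homing to the small intestine, was at 2.21 ± 0.168 against 7.64 ± 1.26 CPM. T cell genes were also counted in these cells at low levels, such as CD2 at 5.25 ± 0.318 CPM in ileum and 21.3 ± 4.12 in jejunum.

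Of 12109 genes tested in B-like cells, 139 passed in edgeR, 32 higher in ileum and 107 higher in jejunum. With the replicate block there were 2476, 1060 higher in ileum and 1416 higher in jejunum. DESeq2 called 680, 247 higher in ileum and 433 higher in jejunum, and subtraction of free RNA left 89. Leaving out jejunum 2 or jejunum 4 gave 2 calls, ileum 4 gave 11, ileum 3 gave 23, jejunum 3 gave 51 and ileum 2 gave 141, of which 2, 2, 10, 22, 42 and 78 were among the 139. The make-up of the class differed as well. Cluster 1 held 33.1% ± 4.18 of ileum B-like cells and 16.5% ± 5.58 of jejunum ones, while cluster 6 held 2.06% ± 0.923 and 17.6% ± 3.01. Within cluster 1 alone 1 gene passed.

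Of 24 lists tested in B-like cells, 14 passed camera, and none with an estimated correlation (lowest adjusted p = 0.151). All 10 MHC class 2 genes had negative changes, with a median of -0.62 (adjusted p = 1.6e-06, and 0.337 with an estimated correlation). Within cluster 1 alone all 10 were negative too, with a smaller median of -0.26 (camera adjusted p = 3.6e-05 at the preset correlation). Over all B-like cells SLA_DRB1 was at 499 ± 92.7 CPM in ileum and 858 ± 8.12 in jejunum. In the T cell list 13 of 14 members had negative changes, with a median of -1.21 (adjusted p = 5.6e-08), and 3 passed the threshold. The interferon list had a median of -0.40, with 1 of its 20 members called, GBP1 at -1.24 ± 0.21. Among 8 members of the antimicrobial list, GUCA2A and GUCA2B, which encode epithelial peptides, were called at low levels, 0.266 and 0.312 CPM in ileum against 2.04 and 2.24 CPM in jejunum. The median of that list was -0.74 (adjusted p = 0.00044), and -0.05 (adjusted p = 0.52) after subtraction of free RNA. The subtracted share was set by epithelial markers, GUCA2A among them. A fall of epithelial genes was thus built in, and the second value does not test free RNA as their source. Epithelial markers were at 29.1 to 40.4 CPM in the lymphocytes of the ileum libraries and at 42.0 to 71.3 CPM in those of jejunum. The dissociation stress list was lower in ileum, with medians of -0.29 in B-like cells, -0.29 in all cells and -0.19 in T/ILC-like cells (camera adjusted p = 0.0036, 0.013 and 0.0021, and 0.491, 0.416 and 0.487 with an estimated correlation). Without jejunum 2 it was called in none of them. The median log2 CPM of its members in B-like cells was 7.17, 7.18 and 7.12 in ileum 2, 3 and 4, and 7.99, 7.26 and 7.22 in jejunum. In T/ILC-like cells it was 7.19, 6.35 and 6.42 in ileum, and 7.44, 6.94 and 6.60 in jejunum. Its member FOS was at 161 ± 10.6 CPM in ileum and 312 ± 73.8 in jejunum B-like cells.

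In antibody-secreting-like cells PHACTR3, ADM, FADS3 and PMEPA1 were higher in ileum by 1.89, 1.85, 1.77 and 1.64. ZP3 was at 927 ± 187 CPM in ileum and 281 ± 30.7 in jejunum (log2 fold change 1.72 ± 0.16, edgeR adjusted p = 0.0058), and ALOX15, an arachidonate lipoxygenase, at 47.3 ± 12.4 against 10.3 ± 4.07. The B cell surface gene CD72 was at 92.6 ± 19.5 against 31.5 ± 13.7 CPM. JCHAIN was at 21172 ± 7698 CPM in ileum and 63329 ± 4599 in jejunum (adjusted p = 0.0060). GZMB, CD52, KDELR3, LGALS1, CD3G, KIF11 and CDCA3 changed by -2.58, -2.11, -2.04, -1.86, -1.84, -1.66 and -1.60. CCL5, a chemokine of cytotoxic T cells, was at 49.2 ± 6.14 against 214.8 ± 80.8 CPM, and the T cell receptor complex gene CD3E at 13.7 ± 7.70 against 46.4 ± 6.01. Whether such T cell genes came from T cells counted with this class was not tested. T/ILC-like cells made up 16.4% of ileum and 32.9% of jejunum cells. Of 8240 genes 658 passed, 336 higher in ileum and 322 higher in jejunum, and 1558 with the replicate block. Cluster 15 held 82.0% ± 6.38 of the class in ileum and 43.2% ± 7.38 in jejunum, and cluster 19 held the rest. ZP3 was among the leading genes of cluster 15, and of B-like cluster 1, and JCHAIN among those of cluster 19. The changes of both genes thus follow the mix of clusters as well as levels within them. In cluster 15, 10 markers of the class were raised, but 0 were among its 10 leading genes. Within cluster 15 alone 10 genes passed and within cluster 19 alone 1 gene. Leaving out jejunum 3 gave 142, ileum 2 gave 176, jejunum 4 gave 248 and ileum 4 gave 253.

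No gene passed in T/ILC-like cells, where edgeR had 195 of 10049 genes at an unadjusted p under 0.05, DESeq2 called 3 and the replicate block gave 5. The 195 in T/ILC-like cells are a smaller share than the 0.05 that chance gives on average. Of 18 lists 10 passed camera in these cells, 3 of them higher in ileum, and none with an estimated correlation (lowest adjusted p = 0.071). No member of these lists was called. The interferon list had positive changes in 18 of 20 members, with a median of 0.35 (adjusted p = 0.0015, and 0.487 with an estimated correlation). The median log2 CPM of its members was 4.86, 3.96 and 6.01 in ileum 2, 3 and 4, and 4.61, 4.47 and 4.63 in jejunum. The list was not called without ileum 4 or without jejunum 4. IFIH1, an RNA sensor, was at 61.8 ± 4.83 CPM in ileum and 53.7 ± 4.03 in jejunum and was not called. MX2, an antiviral gene, was at 33.5 ± 26.0 CPM in ileum and 17.1 ± 1.26 in jejunum, and was not called. B cell genes had a median of 0.45 in T/ILC-like cells, with 10 of 13 members positive and none called (adjusted p = 0.326 with an estimated correlation). Their median log2 CPM there was 3.70, 2.43 and 2.63 in ileum 2, 3 and 4, and 3.06, 2.98 and 2.10 in jejunum, so that only ileum 2 lay above all jejunum libraries. With the replicate block the ILC3 list was no longer called (adjusted p = 0.051) and the MHC class 2 list was (adjusted p = 0.0091).

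**Figure D3:**
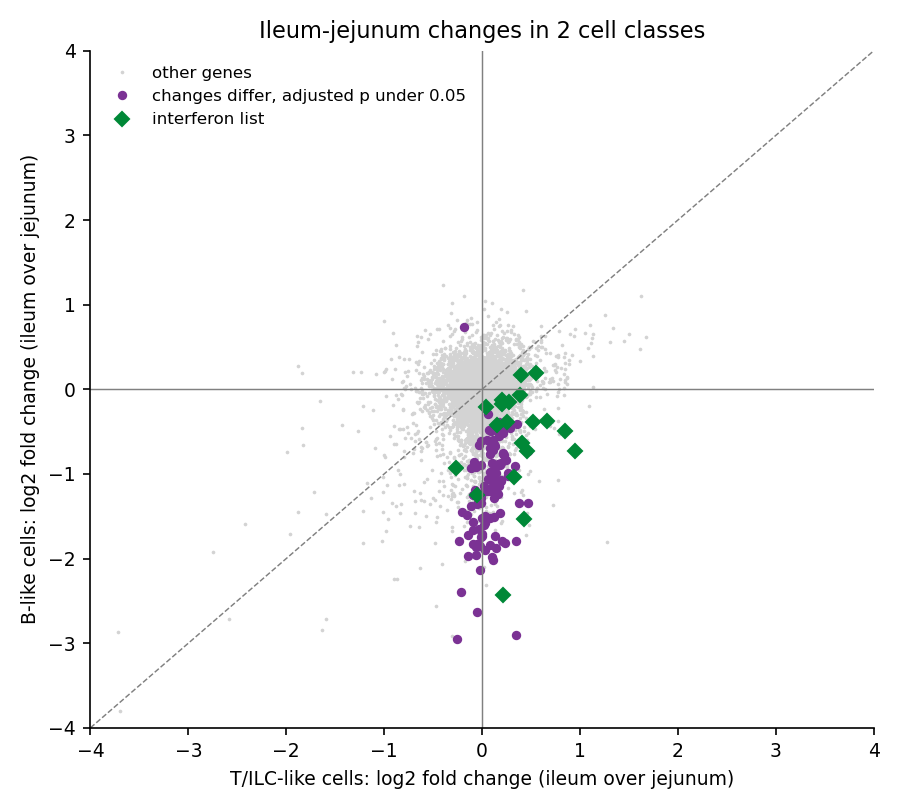
Log2 fold change (ileum over jejunum) of 9785 genes in T/ILC-like cells (horizontal axis) and B-like cells (vertical axis); each point is a gene, with the 113 genes whose changes differed between the classes in purple and the 20 interferon genes in green. YBX3 lay at 0.24 on the horizontal and -1.82 on the vertical axis.

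In myeloid-like cells no gene of 8559 passed in edgeR and 0 in DESeq2. In edgeR 304 had an unadjusted p under 0.05, again a smaller share than chance gives on average. Without ileum 2, edgeR called 2.

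In epithelial-like cells HOXA9, HOXB9 and HOXB7, homeobox genes of the posterior body, were at 41.9 ± 20.0, 40.7 ± 0.251 and 23.8 ± 5.14 CPM in ileum and at 0 CPM in all 3 jejunum libraries. FABP6, the ileal bile acid binding protein, was at 44067 ± 11965 CPM in ileum and 11294 ± 2366 in jejunum (log2 fold change 1.96 ± 0.21, edgeR adjusted p = 0.0063). SULT1E1, a sulfotransferase, was higher in ileum by 5.66, GPRC5A by 3.02, PMP22 by 2.64, DPEP1 by 2.53, and TMIGD1 and SLC5A12 by 2.31 each. In the other direction the peptide hormone gene CCK was at 1.97 ± 2.30 CPM in ileum and 314 ± 374 in jejunum. GCG and SCGN were at 0 CPM in all ileum libraries, and at 2783 ± 2937 and 28.0 ± 9.82 CPM in jejunum. Of 7868 genes 44 passed, 37 higher in ileum and 7 higher in jejunum. Without jejunum 2 there were 38, with 19 higher in each tissue. The replicate block gave 140 and DESeq2 158, and leaving out jejunum 4 gave 16 and jejunum 3 gave 24. The class was small, with 35 to 157 cells per library.

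**Figure D4:**
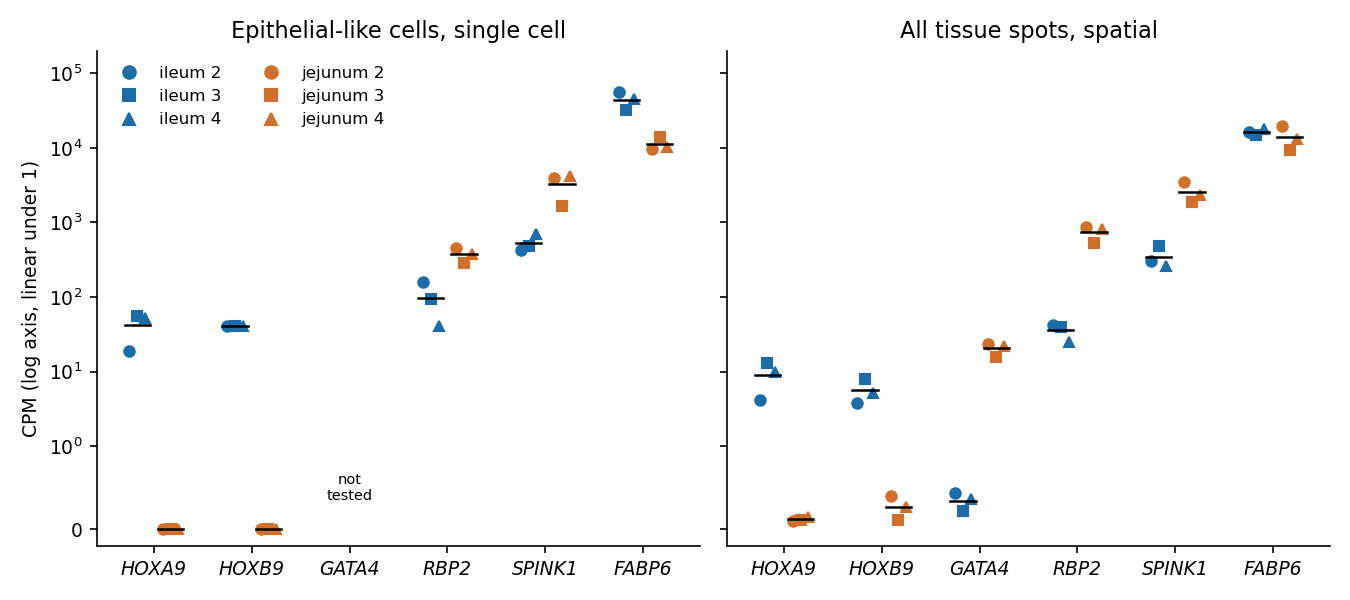
CPM (log axis, linear under 1) of 6 genes per library or section in epithelial-like cells and in whole sections; horizontal lines are means. HOXA9 and HOXB9 lay at 0 in the jejunum libraries, and GATA4 lay below 1 CPM in the ileum sections.

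In whole sections GATA4, a transcription factor of the proximal intestine, was at 0.337 ± 0.112 CPM in ileum and 20.6 ± 4.08 in jejunum (log2 fold change -5.93 ± 0.33, edgeR adjusted p = 0.0020). RBP2, a retinol binding protein of absorptive cells, was at 35.6 ± 9.25 against 737 ± 186 CPM, and PLB1, ENPP3, CREB3L3 and SPINK1 were higher in jejunum too. HOXA9 and HOXB9 were the 2 genes higher in ileum, with log2 fold changes of 6.17 and 4.40, and 1 called gene had no symbol. They fall below the 10 CPM limit of the naming rule and were, like FABP6 here, chosen after their values were seen. FABP6 had a log2 fold change of 0.21 in sections (edgeR adjusted p = 0.81), and the difference from epithelial-like cells was not tested. The 16 other epithelial markers had a median of -0.92 in sections, none of them called.

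All ileum sections lay on 1 slide and all jejunum sections on another. Of 13180 genes in whole sections 9 passed in edgeR, and DESeq2 called 235. With the replicate block there were 15, with 6 of the 9 among them, but the numbers did not pair in sections. Another scaling gave 4. Without jejunum 3 there were 37, without jejunum 4 there was 1, and without any other section 3. Of 26 lists 7 passed camera, and 11 without jejunum 4, but with an estimated correlation every adjusted p was 0.834 or more. The proximal absorption list had negative changes in 23 of 24 members, with 2 called over all genes and 21 lower in ileum when adjusted over the list alone. The B cell, germinal centre, cell cycle and macrophage lists had medians of 0.55, 0.70, 0.36 and 0.38, with no member called. The crypt and antimicrobial lists had medians of -0.64 and -0.42, also with none called. Median, mean and test direction differed in sign for the smooth muscle, interferon and ILC3 lists in sections, the B cell and endothelial lists in B-like cells, the naive cell list in T/ILC-like cells and the enteric nerve list in all cells, none of them called.

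RBP2 and SPINK1 were also called within regions. Region 3, led by CCL19, CXCL13 and CCR7, chemokines and a receptor of T cell zones and follicles, held 7.86% ± 4.70 of ileum spots and 6.50% ± 5.43 of jejunum spots (exact permutation p = 0.9). In it 4 genes passed, SPINK1, RBP2, CYP1B1 and ENPP7, all higher in jejunum, and 8 with the replicate block. CYP1B1 and ENPP7 fall outside the naming rule and were chosen after their values were seen. Without ileum 2 there were 7, and without ileum 3, jejunum 2 or jejunum 4 there were 2. The share difference of 1.36 percentage points went to -0.676 without jejunum 2 and to -0.255 without ileum 4. RBP2 there was at 2.62 ± 1.40 against 52.6 ± 14.7 CPM, far below its level in whole sections in both tissues. Whether RNA of absorptive cells in or near these spots gave this difference was not tested. Section-centred region 10, led by CCL20, ENPP7 and CXCL9, had 17 genes, 6 higher in ileum and 11 higher in jejunum, and 90 with the block. AP3B2 was at 33.0 ± 7.12 CPM in ileum and 2.81 ± 1.40 in jejunum. SPP1, which encodes osteopontin, was at 409 ± 120 CPM in ileum and 41.9 ± 17.7 in jejunum there, and the chemokine CXCL12 at 52.7 ± 5.56 against 17.4 ± 1.42. Without jejunum 4 this region had 2 genes, and without ileum 3 or ileum 4 it had 5. Section-centred region 2 had none in edgeR, 25 in DESeq2, and 2 in edgeR without jejunum 2. In edgeR 475 of its 10509 genes had an unadjusted p under 0.05, a smaller share than chance gives on average.

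The changes of all cells and of whole sections were compared across 12535 genes, which are not independent replicates. Pearson's r was 0.296 and Spearman's rho 0.357. Deviations of a library correlated with those of the equally numbered section of its tissue, at 0.25, 0.21 and 0.25 in ileum 2, 3 and 4. In jejunum the values were 0.24, 0.48 and 0.36. The 2 sets of changes may thus share sample deviations, and no value of r without a tissue effect was computed. All 8 genes called in sections and tested in cells had the same sign in both. Without replicate 2 the value of r was 0.073, and the calls for all cells were then 0. Between epithelial-like cells and sections r was -0.057 and rho -0.285, with the same sign for 39.4% of genes. All 7 genes called in sections and tested in these cells had the same sign, and so had 20 of the 44 called in the cells.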

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

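The tests with free RNA, a mislabelled section and hormone genes were chosen only after the result was seen, as was the section-centred clustering.

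The change between ileum and jejunum differed between B-like and T/ILC-like cells for 113 of 12099 genes, by a test of the difference itself, with 112 of them lower in B-like cells. The difference of log2 fold changes was -2.11 for CD2, -2.05 for YBX3, -1.92 for FAM129A, -1.75 for GNLY, -1.75 for SERPINB9 and 0.92 for TYROBP. After subtraction of free RNA 47 genes passed, and GNLY and SERPINB9, with differences of -2.74 and -1.80 after it, no longer did. Subtraction of the T/ILC-like profile was not run for this test. T cells counted with B-like cells thus stay open as a source of differences for T cell genes such as CD2. Leaving out ileum 2 gave 170 genes, jejunum 4 gave 49, and ileum 4 or jejunum 2 gave 53. Among gene lists 7 differed between these classes at the preset correlation and none with an estimated correlation (lowest adjusted p = 0.165). With 10 splits of the 6 libraries no share under 0.05 can be had. The real split gave 113 genes and the highest other 0, and for lists it gave 7, with as many or more in 3 of 10 splits and 9 in the highest other.

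In B-like cells the T cell list had a median log2 fold change of -1.21 with 3 of 14 members called higher in jejunum, and the absorptive list -1.10 over 18 members with 1 called each way (adjusted p = 0.179 and 0.151 with an estimated correlation). Free RNA in the droplets is argued against as the whole cause for the T cell genes, whose median was -1.43 after its subtraction, with a standard error of 0.304. For the absorptive genes it stays open, with a median of -0.39 and a standard error of 0.462 over the 10 members still tested after its subtraction. Epithelial markers set the share subtracted, so a fall of absorptive genes was partly built in and cannot decide this. T cells counted with B-like cells stay open. CD3 genes put the T/ILC-like share at 0.282% to 0.532% in ileum and 0.607% to 0.869% in jejunum. After its subtraction 6 of the other 11 members were still tested, with a median of -1.30 and a standard error of 0.725. The whole list then had 7 members tested, a median of -0.39 and a camera adjusted p of 0.088. Among related lists, the cytotoxic one was no longer called (adjusted p = 0.57), while the CD4 and naive cell ones were (0.040 and 0.0026). A different mix of B-like clusters stays open too, with a median of -0.70 and a standard error of 0.235 within cluster 1. A difference between the tissues was not tested apart from these.

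In the section-centred clustering 445 absorptive spots of jejunum section 3 fell in region 1 with 381, 359 and 568 spots of the ileum sections, against 1 and 0 spots of jejunum sections 2 and 4. A mislabelled section is argued against, since GATA4 was at 15.9 CPM in jejunum 3 against 0.437, 0.217 and 0.358 in the ileum sections, and HOXA9 at 0.113 against 4.17, 13.1 and 9.80. RBP2 was at 1411 CPM in the jejunum 3 spots of the region and at 69.6 to 118 CPM in its ileum spots. In the absorptive spots of jejunum 2 and 4 it was at 1858 and 2116 CPM. The centring may have caused the grouping in part, though RBP2 does not measure what centring did. Without centring, at resolution 0.3, the region matched to region 13, led by S100G, REG3G and RBP2, held 25.5% of jejunum 3 spots. It also held 17.8% of ileum 3, 0% of ileum 2 and 0.0448% of ileum 4 spots. Some grouping of jejunum 3 with ileum 3 spots thus arose without centring. No biological explanation was tested.

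FABP6 was higher in ileum in epithelial-like cells, at 1.96, and at 0.21 in whole sections. A larger share of epithelium in the jejunum sections may account for part of this and stays open, since the 16 other epithelial markers had a median of -0.92 there, all negative and none called, and FABP6 lay 1.12 above it. Within absorptive spots, FABP6 was at 36533, 31952 and 45525 CPM in ileum and at 40901, 12033 and 25741 CPM in jejunum 2, 3 and 4. The log2 difference was 0.69 with a standard error of 0.54. The spots of ileum and jejunum 3 come from section-centred region 1, and those of jejunum 2 and 4 from section-centred region 3. Epithelial-like cells of another kind in the 2 assays stay open, since GCG changed by -0.17 in sections but was at 0 in all ileum epithelial-like libraries, which leaves no fold to set beside it, and CCK changed by -1.18 in sections and -6.98 in epithelial-like cells, where the prediction counted a smaller change in sections against this explanation although it may go with it. Slide and tissue cannot be told apart here, and a difference between the tissues was not tested further.

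Barcodes not taken as tissue spots held 14.6% (ileum 4) to 30.3% (jejunum 3) of the UMIs of a section and were not used in the comparisons. Since tissue spots were taken by rank of their UMI totals, these are the lowest shares that the number of tissue spots allows, and not measured shares outside the tissue.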

How the results depend on the processing

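Single-cluster sums, the T profile subtraction and list tests on corrected sums were added after seeing the data. Counted per named gene and alternative setting, 8641 results kept their side of the threshold, 597 lost it and 291 gained it. For lists these counts were 849, 136 and 27. Those that kept their side include results called in neither setting. Where no cause is named, the cause was not tested. DESeq2 gave 3346 genes in all cells, 680 in B-like, 3 in T/ILC-like and 158 in epithelial-like cells, 235 in sections, 15 in region 3, 25 and 101 in section-centred regions 2 and 10, and 217 for the difference between classes. Without a filter there were 246 in B-like, 1235 in antibody-secreting-like, 1 in T/ILC-like, 3 in myeloid-like and 301 in epithelial-like cells, 14 in sections, 30 in region 3, 6 and 104 in the section-centred regions and 263 for the difference. Subtraction of free RNA gave 89 genes in B-like cells, 47 for the difference and 9 lists in B-like cells. T profile subtraction gave 91, cluster 1 alone 1, cluster 15 alone 10 and cluster 19 alone 1. With 25% mitochondrial UMIs there were 73 epithelial-like genes and a share difference of -1.55. Another scaling gave 4 genes in sections, and spots of at least 1000 UMIs 3, with 10 in region 3. Resolution 0.3 gave 2 there, and resolution 1.0 gave no value. With an estimated correlation 0 lists passed in each set, and fry called 12 in all cells, 6 in B-like cells, 2 in T/ILC-like cells and 0 in sections, 20 in total.

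With the replicate block there were 4936 genes in all cells, 2476 in B-like, 1558 in antibody-secreting-like, 5 in T/ILC-like and 140 in epithelial-like cells, 8 in region 3 and 90 in section-centred region 10. In sections there were 15, but the numbers did not pair there (0.007, -0.050 and 0.397). The block moved no other count by over 1.5 times, and turned the calls of 3 lists named in the results.

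Of the 139 genes called in B-like cells 8 had the other sign in cluster 1, and of the 658 in antibody-secreting-like cells 61 did in cluster 15 and 125 in cluster 19. Among genes of the naming rule, signs turned for PTPRJ in B-like cluster 1 (-0.0629), and in antibody-secreting-like cells for ISG20 (0.39) and CD22 (-0.15) in cluster 19, GP2 in cluster 15 (-0.15) and CTSH in clusters 15 and 19 (-0.0264 and -0.0583). The T/ILC-like antimicrobial list turned without ileum 3, with camera adjusted p from 0.000769 to 0.426 over the libraries left out, and the smooth muscle list of sections without ileum 2, from 7.0e-05 to 0.923. The region 3 share difference turned with spots of 1000 UMIs (-0.032), at resolution 0.3 (-0.211), without ileum 4 (-0.255) and without jejunum 2 (-0.676).

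Leaving out each sample gave 224 to 1437 genes in all cells, 2 to 141 in B-like, 142 to 532 in antibody-secreting-like, 0 to 2 in myeloid-like and 16 to 50 in epithelial-like cells, 1 to 37 in sections, 2 to 7 in region 3, 0 to 2 and 2 to 21 in section-centred regions 2 and 10, and 49 to 170 for the difference. It gave 7 to 11 lists in sections, a share difference of -0.724 to 0.014 for antibody-secreting-like cells and of -0.676 to 4.44 for region 3. Leaving out a replicate number from both tissues and both assays gave r from 0.073 to 0.430.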

Other observations

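The hypothesis below was formed before its test was run, but after the changes of the interferon list in each class were seen. Its test used the same libraries, so it is not independent of those changes. The list test of the difference between classes was added after seeing the data.

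All 20 members of the interferon list had a lower change between ileum and jejunum in B-like than in T/ILC-like cells, with a median difference of -0.81. The test of the difference gave a camera adjusted p of 4.0e-11, and 0.165 with an estimated correlation, so a difference stays open. In B-like cells the chemokine CXCL10 was at 4.73 ± 3.91 CPM in ileum and 25.8 ± 12.7 in jejunum and was not called, and GBP1, at 22.0 ± 5.77 against 52.0 ± 8.76, was. The median log2 CPM of the list's members was 3.16, 2.32 and 3.28 in ileum 2, 3 and 4, and 3.73, 3.92 and 3.47 in jejunum. In T/ILC-like cells it was 4.86, 3.96 and 6.01 in ileum, and 4.61, 4.47 and 4.63 in jejunum, so that ileum 2 and ileum 4 stood above and ileum 3 below the jejunum libraries. An effect of tissue that differs between the classes may underlie this and stays open as well. Leaving out any library kept the direction, with adjusted p from 7.1e-14 to 5.7e-08. Within B-like cluster 1 the median of the list was -0.09 over 15 members. For the 7 lists called in this test, 3 of the 10 splits of the libraries gave as many, with 9 as the highest other. The other 6 were the T cell, CD4, cytotoxic, naive cell and MHC class 2 lists, with lower changes in B-like cells, and the cell cycle list, at 0.25. For the T cell, CD4, cytotoxic and naive cell lists, T cells counted with B-like cells were not tested as a source of this.

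With 3 samples against 3 there are 10 splits, too few for a share under 0.05. These splits treat the 6 samples as exchangeable and do not keep the pairing inferred from the data. The real split gave 1741 genes in all cells, and the highest other 0. The values were 139 and 0 in B-like cells, 658 and 2 in antibody-secreting-like cells, 44 and 0 in epithelial-like cells, 9 and 0 in sections, 4 and 1 in region 3, and 17 and 1 in section-centred region 10. In these 1 split gave as many, the real one. T/ILC-like cells had 0 against 3, myeloid-like cells 0 against 1, and section-centred region 2 had 0 against 0, so all 10 splits gave as many. For gene lists the values were 22 and 15 in all cells, 14 and 11 in B-like cells and 10 and 7 in T/ILC-like cells. In sections the real split gave 7 lists and 9 of the 10 splits gave as many. The highest, 15, set ileum 2, ileum 3 and jejunum 3 against the rest.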
